A study of Mus musculus with 4 samples.

How the data were processed

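Poly(A) RNA was sequenced from mouse embryonic stem (ES) cells of a mixed C57BL/6 and 129Sv background, cultured in serum with leukemia inhibitory factor. The cells were p53+/+ or p53-/- and were left untreated or given 0.5 uM Adriamycin (doxorubicin, which traps topoisomerase II on DNA) for 8 h, per the labels' protocols. Each of the 4 groups has 1 library. The labels' protocols also name an exome enrichment kit, so the libraries could differ from plain poly(A) libraries in which transcripts they hold.

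The authors deposited 1 table of FPKM per library (fragments scaled to transcript length and to all mapped fragments), laid out as a Cufflinks transcript table per the file headers. The same deposited tables give a lower and an upper bound of each FPKM, the read coverage of each transcript, its length in bases, its position and a quantification status. CASAVA 1.8.1, TopHat2 2.0.5, TopHat and Cufflinks are named, with the mouse build mm9, per the submitters' processing notes, which as used here give no role or order. The version of Cufflinks and the annotation were not given in the sources used here. The deposited values are not counts, so no count test was run.

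Each table has 30769 rows with RefSeq transcript identifiers and no gene names. Names were taken from a RefSeq gene table of the assembly GRCm38 for 30223 rows and from GENCODE release M21 for 184 more, so 30407 rows were named and 362 were not. Because that assembly is not mm9, it was used only for names, for the span of Apela and its distance to Trim61, and for transcript sequences. All positions are those of the deposited tables, in mm9, counted from 1.

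Each gene was represented by its transcript with the highest mean FPKM. Short RNA genes (787 rows) were left out, which left 22416 genes, and 12930 of these had an FPKM of at least 1 in at least 1 library. Of the 12930 genes, 2972 had several transcripts. Differences were taken on the log2(FPKM + 1) scale, which understates the change of low genes. A gene was counted as higher or lower at a difference of at least 1 on that scale. There are no replicates, so no difference has a replicate check, and no p-value or standard deviation is given. The 5 comparisons were the response to Adriamycin in each genotype, the genotypes compared in untreated and in treated cells, and the p53+/+ response minus the p53-/- response.

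The 29 gene lists, the comparisons, the threshold on differences and most alternatives were fixed before the data were examined. The lists were p53 targets of arrest and feedback, of apoptosis, and of DNA repair and metabolism, pluripotency, Wnt, Nodal and BMP, mesendoderm, neuroectoderm, primitive endoderm, trophoblast, fibroblast, 2-cell-like, G2/M, G1/S, DNA repair and checkpoint, immediate early, integrated stress, interferon and NF-kB, BCL2 family, ribosome biogenesis, ribosomal protein, histone, imprinted, sex-linked, DNA methylation, germline, glycolysis, reference gene and apelin lists. A list is described by the median difference of its members past the filter and by the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. A median at percentile 2.50 or below, or 97.5 or above, is called, a limit that was not fixed in advance. Percentiles describe these libraries only. The neuroectoderm list holds epiblast as well as neuroectoderm markers.

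Named genes followed a fixed rule. Trp53, Apela, Apln and Aplnr were reported in every library. Each comparison gave its 10 largest higher and 10 largest lower genes among those with an FPKM of at least 5 in a compared library and status OK, without short RNA genes and unnamed gene models. Each list gave up to 4 members with the largest differences as its possible examples, of which only some are named. Any other gene named was chosen after its values were seen. Some results that the rule would name are not reported.

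The 95% bounds of Cufflinks cover counting and assignment error only. In each library 1525 to 2036 rows with status OK had an FPKM above their own upper bound, so bounds are given for genes of the main measurement only where they hold the FPKM. Depth was estimated as coverage times length summed over transcripts. The calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, and blastn 2.17.0 for sequence matches. They were tested on libraries simulated from the untreated p53+/+ values with a noise SD of 0.15 on the log2 scale, for the p53+/+ response over 11484 genes. All 100 genes changed 4-fold and all 100 changed 8-fold were recovered, and 0 unchanged genes were counted. The changed genes stood at 5 FPKM or more and the noise was an assumed value. This checks the calculations and gives no rate of false calls for these libraries. A simulated raised list of 20 genes lay at percentile 100 and an unchanged one at 23.1.

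The alternatives were pseudocounts of 0.1 and 5 FPKM, no filter or a filter of 5 FPKM, upper quartile, median ratio and quantile scaling, short RNA genes kept, status OK only, transcripts of a gene summed, a 1.5-fold step, and Cufflinks bounds that do not overlap. A pair of alternatives was added after seeing the data, namely only transcripts whose FPKM lies within its bounds, and only genes with introns.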

Results

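Poly(A) RNA of p53+/+ and p53-/- mouse ES cells was compared between untreated cultures and cultures exposed to Adriamycin, at 0.5 uM over 8 h, with 1 library per group and no replicates. The series addresses Apela, a regulatory RNA placed in a feedback loop with p53, the transcription factor that responds to DNA damage. The aligned bases came to 4.32 and 4.15 gigabases in the untreated and treated p53+/+ libraries and to 3.34 and 3.52 gigabases in the p53-/- libraries. Between 11319 and 12165 genes reached 1 FPKM in a library.

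Trp53, the targeted gene (chromosome 11, 69393861 to 69405375 in mm9), was lower but not absent in the cells labelled p53-/-. Its transcripts summed to 216 FPKM in untreated and 165 FPKM in treated p53+/+ cells, against 78.6 and 76.5 FPKM in p53-/- cells. This was 2.75-fold and 2.16-fold more in p53+/+ cells. The main transcript stood at 161 FPKM (95% bounds 156 to 167) in untreated p53+/+ cells and at 43.4 FPKM (40.3 to 46.5) in untreated p53-/- cells. The sources used here do not give the deleted exons, and a sum over the whole transcript cannot show which part of it remained.

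Adriamycin treatment of p53+/+ cells was accompanied by higher transcripts of most p53 targets. Of 19 measured targets of arrest and feedback, 14 were higher and 0 lower, with a median difference of 1.45. Mdm2, which encodes the ubiquitin ligase that degrades p53, went from 32.6 to 257 FPKM, Plk2 from 8.05 to 110 FPKM and Btg2 from 9.46 to 74.4 FPKM. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, went from 25.9 FPKM (24.2 to 27.7) to 83.0 FPKM (79.8 to 87.0). Among 16 targets that act in apoptosis, 11 were higher, with a median of 1.44. Examples were the p53 relative Trp73 (1.33 to 45.5 FPKM), the death receptor Fas (0.253 to 10.5 FPKM) and Apaf1 (3.52 to 24.3 FPKM), the scaffold of the apoptosome. Of 18 targets of DNA repair and metabolism, 10 were higher, with a median of 1.49, among them Dcxr (18.02 to 196 FPKM) and Ephx1 (6.95 to 77.6 FPKM). Fbxw7 differed by 3.62 in its main transcript and by 1.47 with its transcripts summed. All 3 medians lay at percentile 100 of random lists. Over the 12 repair and metabolism targets whose FPKM lies within its own bounds in every library, an alternative added after the data were seen, that median was 0.57 at percentile 99.3.

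Pluripotency genes were lower after Adriamycin in p53+/+ cells. Of 25 members 8 were lower and 0 higher, with a median of -0.82 at percentile 0, or -0.52 with a pseudocount of 5 FPKM. Lin28a, an RNA-binding repressor of let-7, went from 94.8 to 17.6 FPKM, Nr0b1 from 58.1 to 10.6 FPKM, Prdm14 from 18.9 to 3.38 FPKM and Zfp42 from 289 to 84.7 FPKM. Pou5f1, which encodes Oct4 and was looked up after the list was summarised, stood at 948 and 721 FPKM. Some Wnt ligands were higher, with Wnt3 at 0.0374 and 6.82 FPKM and Wnt9a at 0.582 and 10.5 FPKM. In the whole Wnt list 6 of 16 members were higher and 1 lower, with a median of 0.53 at percentile 82.2.

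Other groups were lower in the treated p53+/+ library. Of 25 G2/M genes 4 were lower (median -0.56, percentile 0.05), including the mitotic kinases Plk1 (99.0 to 29.2 FPKM) and Aurka (75.4 to 33.6 FPKM). Ribosome biogenesis genes had a median of -0.59 (3 of 18 lower, with Nop56 and Nop58 among them), which lay at percentile 9.20 over the 8 members within their own bounds, and glycolysis genes one of -0.57 at percentile 0.200 (2 of 17 lower, Hk2 and Eno1). DNA methylation enzymes had a median of -0.70, with 3 of 9 lower, namely Tet2, Dnmt3a and Dnmt3l. The G1/S list was lower in 3 of 25 members, the cyclins Ccne1 (145 to 49.3 FPKM), Ccnd1 and Ccnd3, and its median of -0.21 lay at percentile 33.6.

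In all, 1493 of 12930 genes were higher and 396 lower in the p53+/+ response. The largest higher differences were those of Trp73, Tap1, Apol8, Sytl1, Fosl1, Them5, Matn1, Tmem40, Sbsn and Cpz, from 4.32 to 3.86. Tap1, a peptide transporter of antigen presentation, went from 1.32 to 45.01 FPKM. The largest lower ones included Emp1 (23.1 to 2.21 FPKM), Bmp4 (26.9 to 4.10 FPKM) and Fgf17 (12.6 to 1.64 FPKM), with Lin28a, Nr0b1, Prdm14 and Dmtn completing the 10 at -2.36, -2.35, -2.19 and -2.17. Adam9, Atp10d and Rpl38 were also among them, but at -0.37, -0.43 and -1.24 with transcripts summed, against -3.19, -2.68 and -2.59 in the main transcript. Higher genes made up 79.0% of the genes counted, and 64.4% after quantile normalization, which moved the median of all genes from 0.05 to -0.09.

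In p53-/- cells the same treatment was accompanied by few differences, with 79 genes higher and 91 lower. The counts moved with the pseudocount, to 250 higher and 164 lower at 0.1 FPKM, where the balance turned, and to 22 and 40 at 5 FPKM. It also turned over genes within their own bounds, with 68 higher and 60 lower, and at a 1.5-fold step, with 295 and 283. No member of the 3 p53 target lists was higher or lower, and their medians were 0.10, 0.16 and 0.14, at percentiles 84.5, 95.2 and 92.0. The apoptosis median passed the call with transcripts summed (0.18, percentile 99.2), and the repair and metabolism median over members within their own bounds (0.27, percentile 99.5). Mdm2 stood at 17.7 and 19.9 FPKM, and Cdkn1a at 16.7 FPKM (15.2 to 18.3) and 24.1 FPKM (22.3 to 25.9). G2/M genes were lower here too, with a median of -0.38 at percentile 0 and 4 of 25 members lower. These were Plk1 (106 to 35.4 FPKM), Cdc20, Tpx2 and Aurka (58.3 to 27.9 FPKM). G1/S genes had a small positive median of 0.15 at percentile 100, with 0 of 25 members higher. Glycolysis genes were lower in this genotype as well, with a median of -0.30 at percentile 0.03 and all 17 members below 0. Of these 2 were lower by at least 1, Eno1 (5.74 to 1.39 FPKM) and Ldha (1204 to 599 FPKM), which stood at -0.35 with transcripts summed. Eno1 stood far below Ldha, and whether its reads were placed on other copies was not tested in either genotype. The pluripotency list had a median of -0.11 at percentile 1.24, with 0 of 25 lower, and lost its call after quantile normalization (-0.05, percentile 4.99) and over the 9 members within their own bounds (-0.06, percentile 14.6).

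The ribosomal protein list was lower in the treated p53-/- library, with a median of -0.53 at percentile 0 and 4 of 31 members lower. Only 5 of its members lie within their own bounds in every library. Rps15a went from 22.9 to 3.30 FPKM and Rps19 from 261 to 84.9 FPKM, while Rps15a-ps4, an intronless copy of Rps15a, went from 18.8 to 183 FPKM. Genes without introns made up 3.32% of all genes and 27.8% of the genes that were higher, 22 of 79. The sperm aldolase copies Aldoart2 (0.128 to 43.1 FPKM) and Aldoart1 (1.40 to 66.3 FPKM) led the higher genes. Reads of near-identical copies cannot be told apart with certainty, so these values are uncertain. Mlst8, Arhgap8, Zfand2b, Atp10d and Rpl38 were also among the 10 largest on either side, at 0.01, 0.08, 0.10, 0.05 and 0.02 with transcripts summed. The remaining genes named by size were Pnp2, Amd1, Tubg2, Csl and Pin1rt1 on the higher side, and Atp5k, H2bc11, Fau, Rplp2, Rps21 and Fabp5 on the lower side.

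The responses of the genotypes were then set against each other. The p53+/+ response exceeded the p53-/- response by at least 1 in 1385 genes and fell short of it by at least 1 in 478. The median of this difference was 1.28 for targets of arrest and feedback (15 of 19 at 1 or more), 1.18 for those of apoptosis (10 of 16) and 1.20 for those of repair and metabolism (9 of 18), each at percentile 100. Over the 12 repair and metabolism targets within their own bounds it was 0.38 at percentile 97.4, just short of the call at 97.5. It was -0.69 for pluripotency genes at percentile 0, with 9 of 25 at -1 or less, led by Lin28a at -2.38. For G2/M genes it was -0.17 at percentile 44.0, with 0 of 25 past 1 in either direction, and for glycolysis genes -0.15 at percentile 46.8. G1/S genes did differ, at -0.53 and percentile 0.03, with 3 of 25 at -1 or less, Ccne1, Ccnd1 and Ccnd3. Ribosomal protein genes stood at 0.19 (percentile 99.7, 4 of 31 at 1 or more, led by Rps15a). Only 5 of these members lie within their own bounds, and the values of Rps15a and its copy are uncertain as described above. Genes of the 2-cell-like state stood at 0.63 (0 of 11 at 1 or more and 1 at -1 or less, percentile 99.9, or 93.6 over the 4 members within their own bounds), and ribosome biogenesis genes at -0.56 (1 of 18 at -1 or less, percentile 0.140). The last call was lost with transcripts summed (-0.36, percentile 6.58). The largest positive differences were those of Trp73, Sytl1, Tap1, Them5, Matn1, Apol8, Fosl1, Tmem40, Cpz and Ltb4r2, from 4.34 to 3.80. The largest negative ones, from -5.28 to -3.13, were those of Aldoart1, Aldoart2, Mlst8, Rps15a-ps4, Amd1, Adam9, Pnp2, Lgals3, Tubg2 and Lck. Of these Mlst8, Adam9, Lgals3 and Lck stood at 0.18, -0.49, -1.19 and -1.42 with transcripts summed. Of the 1493 genes higher in p53+/+ cells, 1227 (82.2%) also had a response difference of at least 1, a quantity that contains the p53+/+ response.

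Across the 12930 genes, which are not independent replicates, the responses correlated weakly, with a Pearson r of 0.14 and a Spearman rho of 0.18. They share no library. Genes higher in both numbered 9, against 9.12 for independent lists, and genes lower in both 16, against 2.79. In opposite directions, 5 were higher in p53+/+ and lower in p53-/- cells, against 10.5, and 9 were lower in p53+/+ and higher in p53-/- cells, against 2.42. Genes counted as exceeding were 74.3% of those past 1 in this comparison, and 63.8% after quantile normalization.

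**Figure D1:**
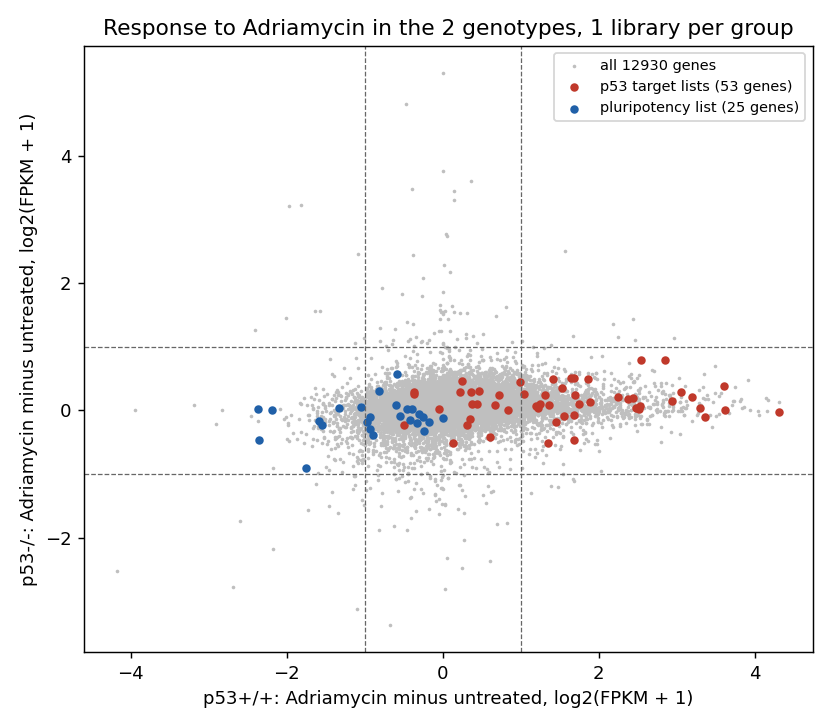
Each point is 1 of 12930 genes, with its log2(FPKM + 1) difference between Adriamycin and untreated cells in p53+/+ cells (x axis) and p53-/- cells (y axis). Dashed lines mark differences of 1 and -1. The p53 target lists in red spread to the right, up to 4.32 for Trp73, the pluripotency list in blue lies mostly to the left, and no gene of these lists passes 1 or -1 on the y axis.

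Apela was not matched by name. The transcript NR_040692 (chromosome 8, 67552316 to 67561235 in mm9) spans 8920 bases and lies 9728 bases from Trim61, and the reference table gives the same span and the same distance for Apela. The identity thus rests on position alone. This transcript went from 12.2 to 2.20 FPKM (1.36 to 2.91) after Adriamycin in p53+/+ cells, a difference of -2.04, and stood at 19.02 and 18.7 FPKM in p53-/- cells. Except in treated p53+/+ cells, its FPKM lay above its own upper bound. That bound was 12.16 FPKM in untreated p53+/+ cells, and 18.55 and 17.67 FPKM in untreated and treated p53-/- cells. The response difference was -2.02. Apln, which encodes a ligand of the receptor Aplnr, stayed between 0.0766 and 0.580 FPKM. Aplnr was listed at 0 in both p53+/+ libraries and reached at most 0.0430 FPKM. Hnrnpl, an RNA-binding protein gene on the apelin list, went from 236 to 172 FPKM in p53+/+ cells and from 190 to 178 FPKM in p53-/- cells, and Hnrnpll from 28.2 to 17.2 FPKM and from 25.9 to 24.5 FPKM.

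Without treatment, p53 targets were lower in p53-/- than in p53+/+ cells. Of 19 arrest and feedback targets 8 were lower (median -0.67, percentile 0), including Trp53inp1 (12.2 against 0.811 FPKM), Eda2r (7.11 against 0.232 FPKM) and Ccng1 (58.1 against 9.62 FPKM). Of 16 apoptosis targets 4 were lower (median -0.55, percentile 0), with Bbc3, which encodes Puma, at 11.01 against 2.19 FPKM, and 1, Tnfrsf23, was higher. Of 18 repair and metabolism targets 5 were lower (median -0.32, percentile 1.27). Over members within their own bounds the apoptosis median was -0.29 at percentile 4.48 and the repair and metabolism median -0.23 at percentile 12.65, so neither kept its call there. The pluripotency list had a median of -0.61 at percentile 0, with 3 of 25 lower, Tfcp2l1, Tbx3 and Rex2, and 1 higher, Dppa3 (2.45 against 36.0 FPKM). The pluripotency medians of the p53+/+ response (-0.82) and of the response difference (-0.69) subtract the same untreated p53+/+ library. High values in that library alone would lower each of these medians, so they are not independent results. Between treated genotypes the pluripotency median was 0.12 at percentile 33.6.

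Markers of several other cell types and cell states also differed between the untreated libraries. Of 15 fibroblast markers 12 were higher and 0 lower in p53-/- cells, with a median of 2.52 at percentile 100, which a pseudocount of 0.1 or 5 FPKM moved to 4.93 or 1.03. The collagen gene Col1a1 stood at 0.727 FPKM in p53+/+ and 151 FPKM in p53-/- cells and Col1a2 at 0.169 and 69.7 FPKM, and Col3a1 was listed at 0 against 21.8 FPKM. Primitive endoderm markers were lower, in 8 of 13 members (median -1.36, percentile 0, or -0.69 with a pseudocount of 5 FPKM), with Gata4 at 5.32 FPKM (4.63 to 5.88) against 0.529 FPKM (0.357 to 0.7002). Genes of the 2-cell-like state were lower in 8 of 11 (median -2.17, percentile 0), among them Zscan4c (115 against 14.2 FPKM), and the near-identical copies of this family make single values uncertain. Trophoblast markers were higher in 4 of 7 (median 1.09) and neuroectoderm markers in 4 of 8 (median 1.13), both at percentile 100, led by Krt18 and by Nes, and without a filter on low values these medians were 0.29 and 0.17. Of 6 mesendoderm markers 1 was higher and 0 lower, with a median of 0.00 at percentile 56.1.

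In all, 473 genes were higher and 443 lower in untreated p53-/- cells. This balance turned with a filter of 5 FPKM, to 299 higher and 358 lower, with a pseudocount of 0.1 FPKM, to 902 and 928, and at a 1.5-fold step, to 1392 and 1488. The largest higher differences were those of Col1a1, Mgp, Col1a2, Bgn, Tnc, Thbs1, S100a4, Col6a1, Col3a1 and Lox, from 6.46 to 4.39, most of which encode extracellular matrix proteins. The largest lower ones were those of Srgn, Spink1, Lgals3, Zscan4a, Zscan4b, Mlst8, Laptm5, Zscan4c, Eng and Trp53inp1. Mlst8 differed by -3.02 in its main transcript and by 0.16 with transcripts summed, and Lgals3 by -3.46 and -1.51.

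After treatment the genotypes differed in more genes, with 917 higher and 1719 lower in p53-/- cells. Arrest and feedback targets were lower in 16 of 19 (median -2.33), apoptosis targets in 13 of 16 (median -1.67) and repair and metabolism targets in 11 of 18 (median -1.49), all at percentile 0, with -0.48 at percentile 1.97 for the last list over members within their own bounds. Plk2 stood at 110 FPKM in p53+/+ and 2.79 FPKM in p53-/- cells, and Trp73 at 45.5 and 0.0671 FPKM. The 10 largest lower differences were those of Trp73, Ptp4a3, Rtkn, Zfp365, Dcxr, Plk2, Psrc1, Eng, Fbxw7 and Trp53inp1, from -5.45 to -4.62, and Fbxw7 stood at -2.50 with transcripts summed. The 10 largest higher ones were those of Col1a2, Mgp, Aldoart2, Aldoart1, Tnc, S100a4, Dppa3, Bgn, Thbs1 and Lox, from 5.65 to 4.40. Lin28a was higher in p53-/- cells (17.6 against 66.4 FPKM), while the pluripotency median of 0.12 lay at percentile 33.6.

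Several of the cell type markers stood apart in the treated libraries as well. Fibroblast markers were higher in 13 of 15 (median 2.50, percentile 100), primitive endoderm markers lower in 9 of 13 (median -1.64, percentile 0) and 2-cell-like genes lower in 10 of 11 (median -2.93, percentile 0). Neuroectoderm markers were higher in 5 of 8 (median 1.37, percentile 100). The trophoblast list was not called here (median 0.23, percentile 84.8), with 2 of 7 members higher and 1 lower. With a pseudocount of 5 FPKM the fibroblast and primitive endoderm medians were 1.32 and -0.89, and over the 4 members within their own bounds the 2-cell-like median was -1.61, against -0.96 in untreated cells. The genotype comparisons therefore hold these groups and the p53 targets side by side. Lower genes outnumbered higher ones, with 34.8% of the counted genes higher, and 44.9% after quantile normalization.

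**Figure D2:**
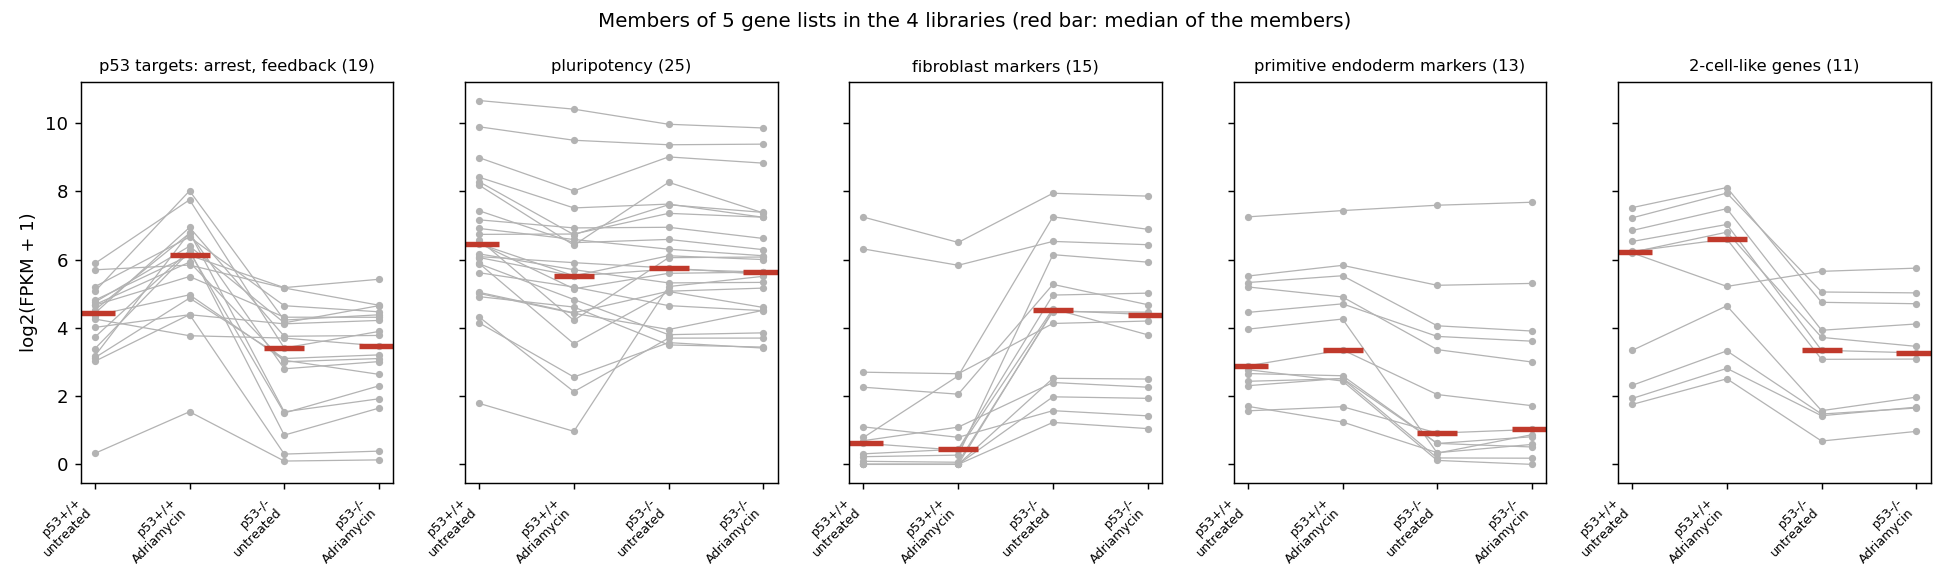
Each grey point is a gene of the named list in 1 of the 4 libraries, on the log2(FPKM + 1) scale, grey lines join the points of a gene, and red bars are the medians of the members. Targets of arrest and feedback peak in treated p53+/+ cells (median difference 1.45 from untreated), whereas fibroblast markers are higher (2.52 in untreated cells), and primitive endoderm (-1.36) and 2-cell-like genes (-2.17) lower, in p53-/- than in p53+/+ cells.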

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

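The tests of ES cell share, of expression within ES cells, of the parents of the copies, of depth, of background reads and of the neighbour share as the main source were chosen only after the result was seen.

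Short RNA genes and an unnamed transcript were outside the main measurement and reached high values. Mir703 was listed at up to 10553.7 FPKM and Snora30 at up to 10256.1 FPKM, with upper bounds of 4.86 and 3.17 FPKM in the same libraries, and Snora64 reached 1585.42 FPKM. The transcript NR_046233 (chromosome 17, 39979942 to 39985774 in mm9) reached 1757.83 FPKM and has no name in the tables used here. Moves in opposite directions in the genotypes, with 1 library each and no test of the difference, gave response differences of -3.13 for Lck, -3.19 for Lgals3, -5.18 for Mlst8 and -5.03 for Rps15a-ps4. With transcripts summed they were -1.42 for Lck, -1.19 for Lgals3 and 0.18 for Mlst8.

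Fibroblast markers were higher in both p53-/- libraries than in both p53+/+ libraries. A lower share of ES cells, which would raise markers of every other cell type, is argued against by the primitive endoderm median of -1.36 in untreated cells. The trophoblast (1.09) and pluripotency (-0.61) medians of untreated cells lie in its direction. So does the neuroectoderm median (1.13), but that list also holds epiblast markers and so need not stand for another cell type. In treated cells the neuroectoderm median (1.37) did too, but the trophoblast (0.23, percentile 84.8) and pluripotency (0.12, percentile 33.6) medians were not called. A lower ES cell share is thus set aside only as the sole source, and a part in the pattern stays open. Fibroblasts in the p53-/- cultures may account for the pattern. Of 18 further fibroblast genes, however, 9 were higher in both treatments, or 50% (exact 95% binomial interval 26.0% to 74.0%). This fell short of the 80% set as the prediction, and it met the 50% or fewer set beforehand as counting against it. The test is read as undecided only because the interval lies on both sides of 50%, a condition that the prediction did not hold. That interval treats the genes as independent. Of the 18 genes 12 were higher in untreated and 10 in treated cells, with medians of 1.786 and 1.255. Of these genes 2, Meox2 and Fap, stayed under 1 FPKM in every library and so could not be counted as higher. Among the others that missed in both treatments, Pcolce and Fstl1 already stood at 53.7 and 18.4 FPKM in untreated p53+/+ cells, and Cxcl12 at 0.318 FPKM. Expression within ES cells that lack p53 cannot be told apart from this, because it predicts the same median of 2.50 in treated cells and each genotype is 1 culture per treatment.

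Genes without introns were frequent among those higher after Adriamycin in p53-/- cells. Among those with a sequence, 16 of 54 with a spliced near-copy were higher (29.6%), against 3 of 295 without one (1.02%), as predicted if reads of the parent genes were placed on their copies in the treated p53-/- library. Of the 16, 3 are RNase P RNA genes matched to Ccnb1ip1 rather than retrocopies. The copies' own transcription stays open, since the median change of the 14 parents was -0.10 with a resampling interval from -0.54 to 0.02. Of these parents 8 were below 0. Aldoart1 gained 64.9 FPKM while its parent Aldoa lost 414 FPKM, but Csl gained 36.9 FPKM while its parent Cs went from 129 to 133 FPKM. Copies that are themselves transcribed could give the same shares, so the shares cannot tell these explanations apart. A difference in read placement in that library thus remains a candidate only. It would also touch ribosomal protein genes such as Rps15a, but the alignment settings of each library were not given in the sources used here.

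Many low-level genes were higher after Adriamycin in p53+/+ cells. Of 9364 genes under 0.5 FPKM in both untreated libraries, 441 (4.71%) reached 1 FPKM in treated p53+/+ cells and 31 (0.331%) in treated p53-/- cells. The treated library held an estimated 0.960 times the aligned bases of the untreated one, so it was not the deeper of them. FPKM is already scaled to all mapped fragments, so this ratio says little about depth as a source of the rise. Olfactory receptor genes gained 0.00905 FPKM on average, against a median of 1.55 FPKM for the 441 genes. This argues against an even rise in background reads as the source, but the 441 genes were selected for their rise. The olfactory mean itself went from 0.0080 to 0.0171 FPKM in p53+/+ cells and from 0.0061 to 0.0063 FPKM in p53-/- cells. A smaller or uneven part of background reads thus stays open. Shared reads or read-through from a raised neighbour may contribute. The 441 genes had a raised gene within 10 kb 3.49 times as often as the other low-level genes (15.0% against 4.29%), but 85.0% had none. This argues against named genes within 10 kb that were counted as higher as the main source. Neighbours further off, unnamed or raised by less than the step would be missed, so they stay open. Activation that depends on p53, directly or not, stays open as untested.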

How the results depend on the processing

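The alternatives of transcripts within their own bounds and of genes with introns only were chosen only after the data were seen. Of 138 alternative gene counts 106 stayed within 1.5 times the main count, of 1665 alternative list medians 1644 stayed within the resampling interval of their members, and 1 called median changed sign. The p53 target and pluripotency medians of the responses stayed within that interval, which is wide for lists of this size. Over members within their own bounds the repair and metabolism median was 0.57 in the p53+/+ response against 1.49, and in the response difference 0.38 against 1.20, at percentile 97.4, where its call was lost. The pluripotency median of the p53+/+ response was -0.52 with a pseudocount of 5 FPKM, and that of the p53-/- response lost its call with quantile normalization (-0.05) and over members within their own bounds (-0.06). In the p53-/- response the apoptosis median gained a call with transcripts summed (0.18), and the repair and metabolism median over members within their own bounds (0.27). A 1.5-fold step, by its construction, counted more genes: 2820 higher and 1482 lower in the p53+/+ response, 295 and 283 in the p53-/- response, 1392 and 1488 between untreated genotypes, 2349 and 3076 between treated genotypes, and 2597 and 1851 in the response difference. A pseudocount of 0.1 FPKM, which weighs low genes more, gave 669 lower in the p53+/+ response, 250 higher and 164 lower in the p53-/- response, 902 higher and 928 lower between untreated genotypes, and 848 lower in the response difference, with fibroblast medians of 4.93 in untreated and 4.52 in treated cells. A pseudocount of 5 FPKM gave 610 higher and 167 lower in the p53+/+ response, 22 and 40 in the p53-/- response, 138 and 123 between untreated genotypes, 343 and 785 between treated genotypes, and 614 and 181 in the response difference, with a fibroblast median of 1.03 in untreated cells. A filter of 5 FPKM, which tests fewer genes, gave 994 higher in the p53+/+ response, 40 in the p53-/- response and 299 between untreated genotypes, where 358 were lower and the balance turned. Quantile normalization gave 624 lower in the p53+/+ response, a Pearson r of 0.089 and a Spearman rho of 0.11, and the cause was not tested. With transcripts summed, 60 genes were lower in the p53-/- response, where Zfand2b stood at 0.10, Atp10d at 0.049 and Rpl38 at 0.023, and Mlst8 stood at 0.16 between untreated genotypes and at 0.18 in the response difference, because other transcripts of these genes moved the opposite way. With transcripts within their own bounds, 60 genes were lower in the p53-/- response. The ribosomal protein median between untreated genotypes was then 0.020 over the 5 members left, against -0.27 at percentile 0.035 over all 31. This is the called median that changed sign. Between treated genotypes the main median of that list was -0.40 at percentile 0. Ldha stood at 8.44 in the p53-/- response with transcripts within their bounds, since another of its transcripts then stands for the gene. No paired analysis was possible because each group has 1 library. Depth of 3.34 to 4.32 gigabases limits low genes most, and without replicates no alternative shows how far a second culture would differ.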

Other observations

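The lists and the split by gene span were planned, and the second set of genes in that split was added after the result was seen.

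Several signalling groups moved in both directions within the p53+/+ response. Of 11 Nodal and BMP genes, Lefty1 (34.3 to 126 FPKM) and Nodal (30.0 to 94.9 FPKM) were higher and Bmp4 was lower, and the median of 0.07 turned to -0.25 with quantile normalization. Mesendoderm genes had Mesp2 (1.37 to 14.7 FPKM) and Mesp1 higher and Eomes lower among 6 measured, with a median of 0.11 that also turned, to -0.24. Of 19 immediate early genes 5 were higher and 2 lower (median 0.46, percentile 99.7), with Fosl1 (0.0811 to 18.2 FPKM) and Fos (1.90 to 12.7 FPKM) higher and Ier3 lower. In the integrated stress list 4 of 16 were lower, Atf4 (95.4 to 35.5 FPKM), Chac1 and Xbp1 among them, and 1, Cebpb, was higher (median -0.45, percentile 0.23). In the p53-/- response this list had a median of -0.17 at percentile 0.05, with 0 of 16 lower, and the response difference of -0.29 lay at percentile 6.44. The interferon and NF-kB list had a median of 0.09 at percentile 47.2, with Cxcl10 at 0.161 and 5.66 FPKM. The BCL2 family had 2 of 13 higher, Bbc3 and Pmaip1, which are also on the p53 apoptosis list (median 0.32, percentile 95.8). DNA repair and checkpoint genes had 0 of 25 past 1 in either direction, with a median of 0.01 that turned to -0.12 with quantile normalization. Imprinted genes were lower in 4 of 20 (median -0.25, percentile 1.85), namely Peg10, Mest, Phlda2 and Snrpn, but with transcripts summed the median was -0.10 at percentile 19.8. Their response difference of -0.33 at percentile 2.10 lost its call in the same way (-0.09, percentile 37.2). Germline genes had 2 of 13 higher, Dpep3 and Tex101 (median -0.02, percentile 22.2). The 2-cell-like list was higher in 2 of 11 (median 0.64, percentile 99.96, or 95.8 over members within their own bounds). In the p53-/- response histone genes (-0.23, percentile 0) and DNA methylation enzymes (-0.18, percentile 0.720) had small called medians with 0 members past 1. The same held for neuroectoderm (-0.15, percentile 0.50) and fibroblast markers (-0.12, percentile 0.14). Neuroectoderm markers were also called in the p53+/+ response (-0.24, percentile 2.35), with 2 of 8 lower and 0 higher.

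Between the untreated genotypes, histone genes were higher in p53-/- cells in 5 of 18 members (median 0.76, percentile 100, or 0.43 with a pseudocount of 5 FPKM), led by H4c4 (8.02 against 27.2 FPKM). Their transcripts mostly lack a poly(A) tail. G2/M genes had a median of -0.37 at percentile 0.02 with 0 of 25 lower, immediate early genes one of 0.48 at percentile 99.98 with 3 of 19 higher and 1 lower, and imprinted genes one of 0.37 at percentile 99.95 with 3 of 20 higher. Igf2, an imprinted growth factor gene, stood at 1.23 against 19.9 FPKM. On the sex-linked list (median -0.44, percentile 4.55) Kdm5d stood at 0.0276 FPKM in p53+/+ and 1.46 FPKM in p53-/- cells, whereas Eif2s3y stood at 35.7 and 30.3 FPKM and Ddx3y at 13.4 and 7.38 FPKM. Reference genes had a median of -0.06 (percentile 28.7), with B2m the exception at 8.55 against 28.9 FPKM.

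Because Adriamycin acts on topoisomerase II, the response was also set out by the genomic span of the gene. In the 10539 genes with at least 1 FPKM in every library, the median response of 3003 genes up to 10 kb long was 0.03 in p53+/+ and 0.05 in p53-/- cells, and that of 245 genes over 200 kb was -0.02 in each. All 6 span classes had medians between -0.07 and 0.03 in p53+/+ cells and between -0.02 and 0.08 in p53-/- cells. This choice leaves out 2391 genes, among them any that fell below 1 FPKM after treatment. Over all 12930 genes, whose median was 0.05 in p53+/+ and 0.07 in p53-/- cells, the class medians lay between -0.01 and 0.09 in both genotypes, with 0.05 and -0.01 for the 347 genes over 200 kb.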
